A study of Mus musculus with 20 samples.

How the data were processed

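Messenger RNA of mouse liver was measured by bulk sequencing in 20 libraries of the substrain C57BL/6NTac. Per the labels' protocols, RNA was extracted with Trizol and magnetic beads, libraries were made with a poly(A) mRNA kit (KAPA mRNA HyperPrep) and adapters that carry unique molecular identifiers, and single-end sequencing used a 51-cycle recipe on a NovaSeq instrument. The deposited table holds expected counts, that is estimated counts per gene that need not be whole: 77.8% of the values of at least 1 were whole. Per the submitters' processing notes the genome build was GRCm38. The aligner, the counting tool, the gene annotation, the use of strand and the use of the molecular identifiers are not given in the sources used here. If the identifiers were not used, amplified copies count as separate reads, so intervals from counts cover counting error only.

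The deposited table had 32422 features, of which 32400 were Ensembl genes and 22 were construct sequences named Neo, LacZ, PGK and the like. The construct features held 7.0 counts over all libraries, a share of 2.2e-06%, and were left out of library sizes and tests. Of the genes, 32325 matched a name in GENCODE mouse release M21, which uses GRCm38, 75 did not, and 98 shared a symbol with another gene. The column of 1 sample that matched no label was not used. Columns were matched to samples by the library name in the labels, and the groups were taken from the diet and treatment labels. Replicate numbers were given in accession order and pair no samples.

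Expected counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr on the 3 groups, which left 13667 genes, and library sizes were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3). Levels are CPM, counts scaled by the TMM-adjusted library size, given as mean ± SD over the libraries of a group. All 3 groups entered 1 quasi-likelihood fit (estimateDisp, robust glmQLFit, glmQLFTest) with 17 residual degrees of freedom and a common biological coefficient of variation of 0.164. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test, with a threshold of 0.05, and every fold change given without another source is on the log2 scale from this fit, with its standard error (SE). The 3 contrasts were gRNA against HFHF control, HFHF control against chow control, and gRNA against chow control.

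The test was tried on simulated counts of 13667 genes with the real genes' means and the real library sizes. In these, 200 genes above a minimum mean level were changed, so the shares recovered hold for genes above that level. The genes of lysosomal hydrolases and membrane proteins were also raised, by a smaller factor. Their calls count in the total of calls but never as false. For the gRNA contrast the test recovered 71.6% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold, and 5.1% of its calls were false. For the diet contrast the shares recovered were 50.7%, 83.6% and 98.5%, with 3% of calls false. For gRNA against chow they were 58.2%, 85.1% and 95.5%, with 1.8% false. Without any simulated change the diet contrast gave 0 and 1 calls in separate simulations and the gRNA contrast 0, and gRNA against chow was not simulated in this way. The real contrasts called 38.6%, 57% and 42.6% of the genes, far more than were changed here. The adjusted threshold depends on how many genes change. So the shares recovered and the shares of false calls do not carry over to the real contrasts.

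Groups, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule names Flcn; for the gRNA and diet contrasts the 8 largest rises and the 8 largest falls (3 each for gRNA against chow) among genes past the threshold with a mean of at least 2 log2 CPM in the higher group and no overlap between the groups' libraries, leaving out gene models without an assigned name; the 3 smallest p-values each way; up to 4 members of smallest p from each list; and, among genes called in both contrasts that meet the same conditions of level and overlap, the 5 largest diet-changed genes moved back and the 5 moved further by the gRNA. Some genes that the rule names are not reported here. For genes with 0 counts in a group only a lower bound is given, against 3 counts over the whole group, and for genes with 1 to 3 counts the ratio of mean CPM is given with a 95% counting interval.

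The 34 gene lists cover the FLCN complex with its Rag-Ragulator and MiT/TFE partners, MiT/TFE targets, the v-ATPase, lysosomal proteins, autophagy, lipogenesis, cholesterol synthesis, fatty acid oxidation, lipid droplets, fructose and glucose handling, mitochondrial respiration, the ATF4 response, the unfolded protein response, extracellular matrix, stellate cells, Kupffer cells, monocyte-derived macrophages, lymphocytes, neutrophils, endothelial cells, cholangiocytes, hepatocyte identity, bile acid handling, interferon-stimulated genes, the acute phase, p53 targets, NRF2 targets, cell cycle, male-biased and female-biased liver genes, the circadian clock, and blood, pancreas and adipose transcripts. Lists were tested with limma 3.58.1's camera, a test of whether a list's genes rank higher or lower than other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 34 lists of a contrast. The same test with a correlation estimated for each list, and fry, were run as alternatives. Calls gained with fry are not given beside each list. The lists overlap, so their results are not independent. Among other shared genes, several MiT/TFE targets are lysosomal, the adipose list shares Cidec and Fabp4 with the lipid droplet list, and Fgb is in both the hepatocyte and the acute phase list. Fnip1, Fnip2, Rragc and Rragd are in both the FLCN complex list and the MiT/TFE target list, which also holds Flcn. The male-biased and bile acid lists share Cyp7b1 and Slco1a1. A list's score in a library is the mean log2 CPM of its members. Single comparisons of few values used two-sided exact permutation tests over all regroupings of the libraries.

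Alternatives were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, limma-voom, dispersion without robust fitting, no low-count filter, a stricter filter (1 CPM in 7 libraries), a fit of the 2 groups alone, a 2-fold minimum, leaving out the library with a different title number, and leaving out each library in turn. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were made with matplotlib 3.10.9. The labels name no vector or guide control without a mouse target, and in the design text the chow group was untreated, so the diet contrast also differs by the vehicle injection. The source of the nuclease, the sex, the age, the time on diet and the hour of sampling are not given in the sources used here.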

Results

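Liver mRNA was sequenced in 20 libraries from C57BL/6NTac mice in 3 groups. The chow control group (n = 5) was untreated and kept on standard chow. Both other groups were put on a high-fat, high-fructose (HFHF) diet. Of these, the HFHF control group (n = 7) received vehicle, phosphate-buffered saline, and the HFHF Flcn gRNA group (n = 8) received an adeno-associated virus with a guide RNA (gRNA) against Flcn. Flcn encodes folliculin, which works with FNIP1 or FNIP2 on the Rag GTPases at the lysosome and through them controls the MiT/TFE transcription factors. Total estimated counts per library were 14131976 to 16285324 for chow, 15244760 to 18194089 for HFHF control and 13974379 to 19586576 for gRNA. The 10 most abundant genes took 21.3 to 28.0% of a library. All 59 pairs of libraries within groups differed by more than sampling noise (lowest chi-square per degree of freedom 12.3, correlation of log2 CPM 0.965 to 0.987), so none was counted as a repeat. The design text speaks of mice, but the labels do not say that each library came from a separate animal, and p-values measure the spread between these samples.

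On the first principal component, with 45.3% of the variance, the chow libraries lay at scores of 55.1 to 68.3, the HFHF control libraries at -52.2 to -31.8 and the gRNA libraries between them at -21 to 13.6. On the second, with 17.9%, the gRNA libraries lay at 15 to 43.8 and the others at -30.4 to -10.7. The title of gRNA replicate 8 differs from every other title in the number of its second field. Of all libraries, replicate 8 had the highest share of the 10 most abundant genes (28.0%) and the lowest share of the albumin gene Alb (2.81%). With gRNA replicate 5 it formed the pair of lowest correlation (0.965). The title number may mark a batch, but with 1 library of 1 group no value within it can be given, and the batch and the group cannot be told apart for that library. Without it 5281 genes passed in the gRNA contrast, 7855 in the diet contrast and 5642 in gRNA against chow, of which 4883, 7484 and 5329 were among those called with it.

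Flcn (ENSMUSG00000032633, GRCm38 chromosome 11, 59791408 to 59810016, minus strand) was measured in every library. Its level was 22.2 ± 6.03 CPM in chow control (n = 5), 20.7 ± 2.98 CPM in HFHF control (n = 7) and 17.8 ± 2.40 CPM in HFHF Flcn gRNA (n = 8). The 5 chow libraries held 32.4, 22.5, 18.6, 20.3 and 17.3 CPM. The 7 HFHF control libraries held 18.9, 17.8, 22.8, 20.5, 19.9, 18.8 and 26.4 CPM, and the 8 gRNA libraries 18.7, 18.8, 14.1, 17.4, 15.2, 18.3, 17.7 and 21.97 CPM. With the gRNA Flcn differed from HFHF control by -0.22 (SE 0.12, 95% interval -0.46 to 0.01, adjusted p = 0.140), and an exact permutation test of log2 CPM gave p = 0.0472 over 6435 regroupings. Diet gave -0.10 (SE 0.13, adjusted p = 0.547; exact permutation p = 0.676 over 792 regroupings), with the opposite sign without chow replicate 1 (0.11). Against chow the gRNA group was at -0.32 (SE 0.13, adjusted p = 0.04999, just under the threshold; exact permutation p = 0.0692 over 1287 regroupings), and without chow replicate 1 the value was -0.12 (adjusted p = 0.419). A guide RNA directs a nuclease to its target, and small insertions or deletions there need not lower the transcript. The guide's position is not given in the sources used here, so transcript level is no measure of editing.

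Of 14 measured partners of Flcn, the genes of the FNIP, Rag-Ragulator and MiT/TFE list, 4 rose with the gRNA, 2 fell and 8 did not pass (the same counts adjusted over the list alone). Of the 3 with the smallest p, Fnip2 rose from 32.3 ± 5.32 to 124 ± 52.4 CPM (log2 fold change 1.94, SE 0.22, adjusted p = 2.43e-06), Rragd, which encodes the Rag GTPase RagD, from 13.5 ± 3.95 to 51.8 ± 17.9 CPM (log2 fold change 1.94, SE 0.22, adjusted p = 1.76e-06), and Fnip1 from 38.2 ± 4.86 to 62.2 ± 6.38 CPM (log2 fold change 0.70, SE 0.08, adjusted p = 1.17e-06).

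**Figure D1:**
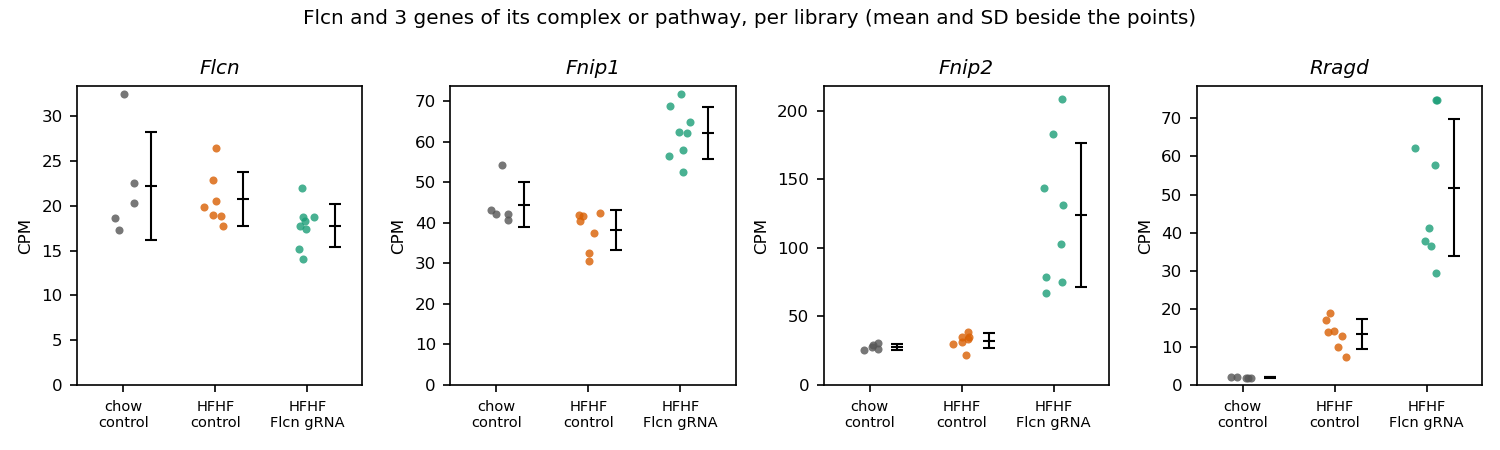
Level of Flcn, Fnip1, Fnip2 and Rragd in CPM (vertical axis, from 0) in each library of the chow control, HFHF control and HFHF Flcn gRNA groups, 1 point per library, with mean and SD beside the points. Flcn overlaps between the groups, with means of 22.2, 20.7 and 17.8 CPM, while Fnip2 has a mean of 124 CPM with the gRNA and 32.3 CPM in HFHF control.

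The first comparison asks what the Flcn gRNA changed in the liver of mice on the HFHF diet. Fabp3 (chromosome 4, 130308595 to 130315463), the fatty acid binding protein of heart muscle, rose from 0.617 ± 0.278 CPM in HFHF control to 37.8 ± 4.70 CPM with the gRNA (log2 fold change 5.92, SE 0.17, adjusted p = 3.34e-17). Cox8b, a cytochrome c oxidase subunit of heart and skeletal muscle, rose from 0.0490 ± 0.0710 to 33.0 ± 24.5 CPM (log2 fold change 9.26, SE 0.67, adjusted p = 2.20e-08), and the fitted value was 9.92 without HFHF control replicate 2. Other genes with the largest rises were the matrix metalloproteinase gene Mmp27 (5.61, SE 0.36), Cyp46a1, which encodes cholesterol 24-hydroxylase (5.20, SE 0.36), the potassium channel gene Kcnk3 (5.21, SE 0.28), the lectin gene Clec2h (5.38, SE 0.55) and Bex2 (6.47, SE 0.41). Nat8f7 was at 6.67 (7.51 without HFHF control replicate 1), and its reads are uncertain because the Nat8 family has near-identical members. Wdr91, an endosomal protein, rose from 12.0 ± 0.395 to 32.6 ± 4.96 CPM (log2 fold change 1.45, SE 0.09, adjusted p = 2.45e-10). For each of these genes every gRNA library lay above every HFHF control library.

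Genes that fell most with the gRNA included Col1a1 (chromosome 11, 94936224 to 94953042), a chain of fibrillar collagen, which went from 82.5 ± 28.2 to 9.01 ± 4.30 CPM (log2 fold change -3.20, SE 0.26, adjusted p = 6.53e-08). Serpina7, which encodes thyroxine-binding globulin, went from 319 ± 44.3 to 32.7 ± 11 CPM (log2 fold change -3.28, SE 0.21, adjusted p = 3.35e-09), and Mmp12, the macrophage metalloelastase, from 41.7 ± 19.5 to 5.26 ± 3.56 CPM (log2 fold change -3.00, SE 0.41, adjusted p = 2.26e-05). The squamous differentiation gene Sprr1a (-4.67, SE 0.49), the adaptor gene Shc2 (-4.27, SE 0.40), the tubulin gene Tubb2b (-3.88, SE 0.42), the syntenin gene Sdcbp2 (-2.77, SE 0.25) and the carbonyl reductase gene Cbr3 (-2.75, SE 0.32) completed the 8 largest falls. Krt8 and Krt18, the keratins of hepatocytes, were among the 3 falls of smallest p, with Krt8 at log2 fold change -1.34, SE 0.09, adjusted p = 4.29e-10 and Krt18 at log2 fold change -1.37, SE 0.09, adjusted p = 7.63e-10, although reads of both can be split with processed pseudogenes. For each gene of this paragraph every gRNA library lay below every HFHF control library.

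Of 13667 genes tested, 2673 were higher and 2597 lower with the gRNA, 5270 or 38.6% in all, and 6376 had an unadjusted p under the same threshold. With upper-quartile scaling the higher genes made up 37.8% of the calls in place of 50.7%. At least 2-fold changes were fewer among the higher genes, with 280 higher and 779 lower. In 689 genes every gRNA library lay above and in 821 below every HFHF control library, 11% of the genes, where chance gives 0.0311%.

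Lysosomal genes and targets of the MiT/TFE factors were higher with the gRNA. For the list of MiT/TFE targets and genes that respond to loss of FLCN, 11 of 21 measured members rose, 0 fell and 10 did not pass (12 higher and 0 lower adjusted over the list alone). This list shares Fnip1, Fnip2, Rragc and Rragd with the partners of Flcn above, so the counts of both lists are not independent. The median was 0.46 (camera adjusted p = 2.77e-06, and adjusted p = 0.220 with an estimated correlation). Mcoln1, the lysosomal calcium channel, went from 19.8 ± 1.63 to 33.1 ± 6.09 CPM (log2 fold change 0.74, SE 0.10, adjusted p = 3.56e-06). Among lysosomal hydrolases and membrane proteins, 26 of 45 measured members rose, 2 fell and 17 did not pass (27 higher and 3 lower adjusted over the list alone). A median of 0.25 gave camera adjusted p = 1.45e-07, or adjusted p = 0.228 with an estimated correlation. Ctsa, which encodes the lysosomal protective protein cathepsin A, was at 0.83, SE 0.10. Of the lysosomal v-ATPase, the proton pump, 12 of 17 measured members rose, 0 fell and 5 did not pass (the same counts adjusted over the list alone). Their median was 0.23 on the log2 scale, with camera adjusted p = 5.51e-04, and adjusted p = 0.284 with an estimated correlation. Atp6v1a was at 0.46, SE 0.07. Autophagy genes had 12 higher and 1 lower of 31 measured members, the same adjusted over the list alone. The median was 0.17 (camera adjusted p = 0.00158, and adjusted p = 0.220 with an estimated correlation). Gabarapl1, which encodes an autophagosome protein, was at 0.96, SE 0.14. The list of the FLCN complex, Rag-Ragulator and MiT/TFE factors itself did not pass, with 4 higher and 2 lower of 14 measured members, the same adjusted over the list alone. A median of 0.05 gave camera adjusted p = 0.0656, or adjusted p = 0.291 with an estimated correlation. It passed without gRNA replicate 1, 3 or 5 (adjusted p = 0.0454, 0.0418 and 0.0343) and without a low-count filter (0.0279).

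Mitochondrial and hepatocyte metabolic genes were higher as well. Of genes of mitochondrial respiration and biogenesis, 26 of 30 measured members rose, 0 fell and 4 did not pass (28 higher and 0 lower adjusted over the list alone). Their median was 0.42 on the log2 scale, with camera adjusted p = 1.35e-10, and adjusted p = 0.220 with an estimated correlation. Ndufs1 of complex I was at 0.55, SE 0.06, Sdha of complex II at 0.48, SE 0.06 and Atp5a1 of the ATP synthase at 0.58, SE 0.07. Of fatty acid oxidation and ketogenesis genes, 19 of 30 measured members rose, 1 fell and 10 did not pass (22 higher and 1 lower adjusted over the list alone). The median was 0.29 (camera adjusted p = 7.23e-06, and adjusted p = 0.308 with an estimated correlation). Ppara, the nuclear receptor that induces fatty acid oxidation, went from 90.3 ± 15.1 to 156 ± 21.7 CPM (log2 fold change 0.79, SE 0.10, adjusted p = 4.29e-06), and Cyp4a10, a fatty acid hydroxylase under its control, was at 1.76, SE 0.22. Bile acid and xenobiotic genes had 12 higher and 0 lower of 22 measured members, or 15 and 0 adjusted over the list alone. A median of 0.64 gave camera adjusted p = 1.95e-05, or adjusted p = 0.220 with an estimated correlation. The uptake transporter genes Slc10a1 (1.07, SE 0.15) and Slco1b2 (0.70, SE 0.09) rose. Hepatocyte identity genes had 9 higher and 2 lower of 22 measured members, or 11 and 2 adjusted over the list alone. Their median was 0.23 on the log2 scale, with camera adjusted p = 0.00466, and adjusted p = 0.308 with an estimated correlation. Cyp1a2 was at 1.68, SE 0.16, while the transferrin gene Trf fell (-0.33, SE 0.08). Male-biased liver genes had 7 higher and 0 lower of 14 measured members, or 8 and 0 adjusted over the list alone. The median was 0.94 (camera adjusted p = 0.00845, and adjusted p = 0.57 with an estimated correlation). Nudt7 was at 1.03, SE 0.18. The male-biased scores of the gRNA libraries spread from 4.25 to 7.70 and overlapped those of HFHF control, from 4.08 to 6.66.

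Extracellular matrix genes fell together with the gRNA: 0 of 26 measured members rose, 26 fell and 0 did not pass (the same counts adjusted over the list alone). A median of -1.54 gave camera adjusted p = 2.56e-40, or adjusted p = 0.00988 with an estimated correlation. No other list of the 34 kept its call with an estimated correlation in this contrast. Col1a2 went from 81.4 ± 20.4 to 14.8 ± 4.93 CPM (log2 fold change -2.46, SE 0.19, adjusted p = 2.02e-08), Col6a1 was at -1.77, SE 0.14 and Thbs1, thrombospondin, at -1.74, SE 0.16. Markers of hepatic stellate cells, the main matrix-producing cells of the liver, had 0 higher and 9 lower of 12 measured members, the same adjusted over the list alone. Their median was -0.60 on the log2 scale, with camera adjusted p = 1.99e-06, and adjusted p = 0.148 with an estimated correlation. Cygb (-1.43, SE 0.13) and Pdgfrb (-1.13, SE 0.13) fell with the smallest p. Markers of monocyte-derived and lipid-associated macrophages had 0 higher and 10 lower of 14 measured members, or 0 and 11 adjusted over the list alone. The median was -1.37 (camera adjusted p = 2.19e-07, and adjusted p = 0.148 with an estimated correlation). Examples were Itgam (-1.87, SE 0.21) and the chemokine receptor genes Cx3cr1 (-2.25, SE 0.26) and Ccr2 (-1.91, SE 0.23). Beside these, markers of sinusoidal endothelial cells had 3 higher and 1 lower of 13 measured members, the same adjusted over the list alone. A median of 0.26 gave camera adjusted p = 0.331, or adjusted p = 0.917 with an estimated correlation. Stab2 rose (0.80, SE 0.10).

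Interferon-stimulated, acute phase, cell cycle and NRF2 target genes were lower with the gRNA. Of interferon-stimulated genes, 1 of 23 measured members rose, 19 fell and 3 did not pass (1 higher and 20 lower adjusted over the list alone). Their median was -0.71 on the log2 scale, with camera adjusted p = 5.29e-09, and adjusted p = 0.220 with an estimated correlation. Isg15 was at -1.11, SE 0.13 and Oasl2 at -1.32, SE 0.16. Cell cycle genes had 0 higher and 16 lower of 20 measured members, the same adjusted over the list alone. The median was -0.90 (camera adjusted p = 1.45e-07, and adjusted p = 0.220 with an estimated correlation). The kinase gene Cdk1 went from 3.20 ± 0.958 to 1.13 ± 0.436 CPM (log2 fold change -1.49, SE 0.22, adjusted p = 1.57e-05). Acute phase genes had 3 higher and 11 lower of 18 measured members, or 4 and 12 adjusted over the list alone. A median of -0.49 gave camera adjusted p = 0.00154, or adjusted p = 0.397 with an estimated correlation. Hp, haptoglobin, went from 3861 ± 513 to 1967 ± 348 CPM (log2 fold change -0.97, SE 0.13, adjusted p = 5.11e-06), and Orm2, whose reads can be shared with its paralogs, was at -1.98, SE 0.27. NRF2 targets had 1 higher and 10 lower of 17 measured members, or 1 and 11 adjusted over the list alone. Their median was -0.55 on the log2 scale, with camera adjusted p = 0.00213, and adjusted p = 0.291 with an estimated correlation. Srxn1, sulfiredoxin, was at -1.01, SE 0.11. Some leukocyte markers were also lower. Monocyte-derived macrophage markers had 0 higher and 10 lower of 14 measured members (median -1.37, camera adjusted p = 2.19e-07, and adjusted p = 0.148 with an estimated correlation). Neutrophil markers had 0 higher and 3 lower of 4 (median -1.02, camera adjusted p = 0.0527, and adjusted p = 0.220 with an estimated correlation), while Kupffer and lymphocyte markers went both ways.

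Other lists did not pass in this contrast. Cholesterol synthesis had 3 higher and 5 lower of 25 measured members, the same adjusted over the list alone. The median was -0.01 (camera adjusted p = 0.819, and adjusted p = 0.955 with an estimated correlation). Lipogenesis had 4 higher and 2 lower of 23 measured members, the same adjusted over the list alone. A median of 0.00 gave camera adjusted p = 0.712, or adjusted p = 0.955 with an estimated correlation. Within lipogenesis Dgat2, which makes triglyceride, rose (0.85, SE 0.09) and so did Acacb (1.40, SE 0.22). Lipid droplet genes had 3 higher and 6 lower of 18 measured members, or 4 and 6 adjusted over the list alone. Their median was -0.08 on the log2 scale, with camera adjusted p = 0.249, and adjusted p = 0.658 with an estimated correlation. Cidea, a lipid droplet protein, fell (-2.20, SE 0.37). ATF4 targets had 2 higher and 9 lower of 20 measured members, or 3 and 9 adjusted over the list alone. The median was -0.35 (camera adjusted p = 0.100, and adjusted p = 0.228 with an estimated correlation). The list passed without a low-count filter (adjusted p = 0.0222). Asns, asparagine synthetase, fell (-1.95, SE 0.32) and Nupr1 rose (2.20, SE 0.20). Fructose, glucose and glycogen genes had 7 higher and 4 lower of 21 measured members, the same adjusted over the list alone. A median of 0.22 gave camera adjusted p = 0.278, or adjusted p = 0.658 with an estimated correlation. p53 targets had 0 higher and 3 lower of 16 measured members, or 0 and 2 adjusted over the list alone. Their median was -0.18 on the log2 scale, with camera adjusted p = 0.181, and adjusted p = 0.658 with an estimated correlation. The list passed without gRNA replicate 6 (adjusted p = 0.0323), and Cdkn1a fell (-1.48, SE 0.26). Of 17 unfolded protein response genes none passed (median -0.00, camera adjusted p = 0.819, adjusted p = 0.955 with an estimated correlation), where the camera direction was up and the median below 0.

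**Figure D2:**
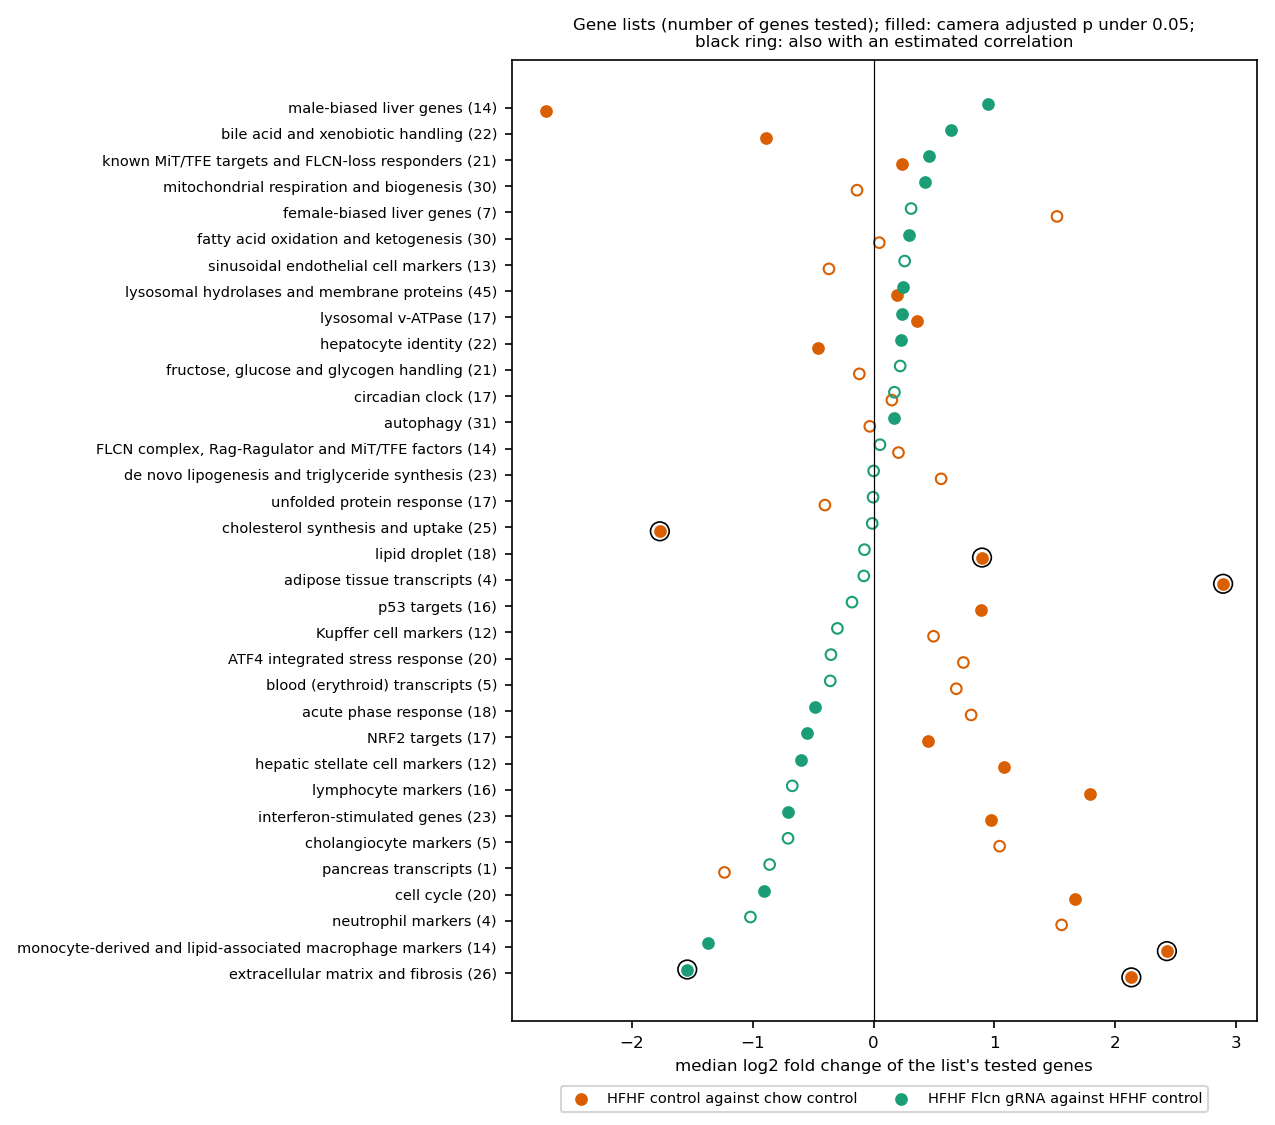
Median log2 fold change (horizontal axis) of each gene list, with the number of genes tested in brackets, for HFHF control against chow control (orange) and HFHF Flcn gRNA against HFHF control (green). Filled points passed camera with the preset correlation and ringed points also with an estimated one: extracellular matrix is ringed in both, at 2.14 with diet and -1.54 with the gRNA.

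The second comparison asks what the HFHF diet with vehicle changed against untreated chow. Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 0.102 ± 0.0650 CPM in chow control to 46.1 ± 25.9 CPM in HFHF control (log2 fold change 8.71, SE 0.88, adjusted p = 2.47e-07). The lipid droplet genes Cidea and Cidec rose from 0.160 ± 0.0570 to 48.4 ± 21.2 CPM (log2 fold change 8.16, SE 0.80, adjusted p = 1.60e-07) and from 0.653 ± 0.431 to 80.3 ± 7.77 CPM (log2 fold change 6.94, SE 0.36, adjusted p = 5.32e-11). Sprr1a had 0 counts in the chow libraries and was at least 235-fold higher in HFHF control, against a floor of 3 counts over the chow group. With 3 chow counts each, Sdcbp2 was 224 times (95% counting interval 76.7 to 1087) and Shc2 194 times (66.3 to 939) its chow level. Without chow replicate 2 the fitted log2 value of Sdcbp2 went from 7.58 to 8.57, which is no bound either. Ly6d (8.30, SE 0.72) and Mmp12 (7.18, SE 0.77) were also among the 8 largest rises. The 3 rises of smallest p were Ubd, a ubiquitin-like protein (log2 fold change 5.10, SE 0.25, adjusted p = 1.29e-12), Gramd1b, a sterol transfer protein (log2 fold change 2.87, SE 0.15, adjusted p = 3.92e-12), and Unc5b, a netrin receptor (log2 fold change 2.62, SE 0.15, adjusted p = 1.55e-11).

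Sqle, squalene epoxidase of cholesterol synthesis, fell from 75.8 ± 15.5 to 1.16 ± 0.933 CPM (log2 fold change -6.06, SE 0.31, adjusted p = 5.32e-11), and Adgrf1, an adhesion G protein-coupled receptor, from 9.59 ± 3.86 to 0.0630 ± 0.0400 CPM (log2 fold change -7.11, SE 0.60, adjusted p = 8.05e-09). The other 6 largest falls belong to families of near-identical copies, so reads may be split between members: Hsd3b5 (-7.49, SE 1.30), Mup12 (-6.00, SE 1.15), Mup1 (-5.61, SE 0.99), Mup7 (-5.50, SE 1.22), Serpina1e (-5.42, SE 1.03) and Mup11 (-5.31, SE 0.84). Without HFHF control replicate 2 these values were -9.31, -7.98, -6.83, -7.52, -6.08 and -6.19. The major urinary proteins, encoded by the Mup genes, are male-biased secreted liver proteins.

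Of 13667 genes tested, 3847 were higher and 3947 lower on the diet, 7794 or 57% in all, and 8368 had an unadjusted p under the same threshold. Upper-quartile scaling gave 60.7% higher calls in place of 49.4%. At least 2-fold changes were 1792 higher and 578 lower. In 2571 genes every HFHF control library lay above and in 2479 below every chow library, 37% of the genes, where chance gives 0.253%.

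Cholesterol synthesis fell as a group: 0 of 25 measured members rose, 24 fell and 1 did not pass (the same counts adjusted over the list alone). The median was -1.77 (camera adjusted p = 3.44e-45, and adjusted p = 7.06e-04 with an estimated correlation). The synthesis enzymes Msmo1, Nsdhl and Cyp51 were the 3 falls of smallest p in the whole contrast, Msmo1 going from 254 ± 38.9 to 26.7 ± 3.58 CPM (log2 fold change -3.25, SE 0.10, adjusted p = 5.07e-16), with Nsdhl at -2.70, SE 0.11 and Cyp51 at -2.96, SE 0.12. Lipid droplet genes rose: 16 of 18 measured members rose, 0 fell and 2 did not pass (the same counts adjusted over the list alone). A median of 0.90 gave camera adjusted p = 2.79e-08, or adjusted p = 0.0486 with an estimated correlation. Plin4, perilipin 4, was at 3.37, SE 0.25. Of lipogenesis genes, 11 of 23 measured members rose, 8 fell and 4 did not pass (the same counts adjusted over the list alone). Their median was 0.56 on the log2 scale, with camera adjusted p = 0.133, and adjusted p = 0.750 with an estimated correlation. Scd1, stearoyl-CoA desaturase, rose (2.12, SE 0.18) and Acss2, acetyl-CoA synthetase, fell (-2.03, SE 0.16). Fructose, glucose and glycogen genes had 9 higher and 6 lower of 21 measured members, or 9 and 8 adjusted over the list alone. The median was -0.12 (camera adjusted p = 0.515, and adjusted p = 0.774 with an estimated correlation). The fructose enzymes Khk (0.55, SE 0.09) and Tkfc (1.04, SE 0.11) rose. Fatty acid oxidation genes had 10 higher and 8 lower of 30 measured members, the same adjusted over the list alone. A median of 0.05 gave camera adjusted p = 0.525, or adjusted p = 0.870 with an estimated correlation. Fgf21, a hormone secreted by the liver, rose (3.93, SE 0.40, and 4.62 without chow replicate 4).

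Matrix, macrophage and proliferation genes were higher on the diet. Of extracellular matrix genes, 26 of 26 measured members rose, 0 fell and 0 did not pass (the same counts adjusted over the list alone). Their median was 2.14 on the log2 scale, with camera adjusted p = 1.96e-27, and adjusted p = 0.0354 with an estimated correlation. Col1a2 went from 6.79 ± 1.05 to 81.4 ± 20.4 CPM (log2 fold change 3.59, SE 0.24, adjusted p = 1.10e-09). Timp1, an inhibitor of metalloproteinases with 0 chow counts, was at least 82.3-fold higher, and with Timp1 at its bound the list's median stayed 2.14. Stellate cell markers had 11 higher and 0 lower of 12 measured members, or 12 and 0 adjusted over the list alone. The median was 1.08 (camera adjusted p = 1.74e-06, and adjusted p = 0.0613 with an estimated correlation). Cygb was at 2.12, SE 0.17. Markers of monocyte-derived macrophages had 13 higher and 0 lower of 14 measured members, the same adjusted over the list alone. A median of 2.43 gave camera adjusted p = 2.09e-09, or adjusted p = 0.0484 with an estimated correlation. Examples were Cd9 (1.63, SE 0.15), Trem2 (5.49, SE 0.51) and Ccr2 (3.20, SE 0.31). Cell cycle genes had 19 higher and 0 lower of 20 measured members, the same adjusted over the list alone. Their median was 1.67 on the log2 scale, with camera adjusted p = 3.21e-08, and adjusted p = 0.161 with an estimated correlation. Top2a, topoisomerase, was at 2.52, SE 0.29. Interferon-stimulated genes had 19 higher and 1 lower of 23 measured members, or 19 and 2 adjusted over the list alone. The median was 0.98 (camera adjusted p = 4.63e-06, and adjusted p = 0.256 with an estimated correlation). NRF2 targets had 11 higher and 3 lower of 17 measured members, the same adjusted over the list alone. A median of 0.45 gave camera adjusted p = 0.00421, or adjusted p = 0.347 with an estimated correlation. For p53 targets there were 11 higher and 2 lower of 16 measured members, the same adjusted over the list alone. Their median was 0.89 on the log2 scale, with camera adjusted p = 0.00430, and adjusted p = 0.347 with an estimated correlation. Cdkn1a was at 2.43, SE 0.33 and Eda2r at 3.94, SE 0.52. Beside these, sinusoidal endothelial markers had 2 higher and 6 lower of 13 measured members, or 2 and 7 adjusted over the list alone. The median was -0.37 (camera adjusted p = 0.385, and adjusted p = 0.784 with an estimated correlation). Kdr, the VEGF receptor, fell (-0.91, SE 0.19).

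Hepatocyte genes were lower on the diet. Of hepatocyte identity genes, 0 of 22 measured members rose, 15 fell and 7 did not pass (0 higher and 16 lower adjusted over the list alone). A median of -0.46 gave camera adjusted p = 2.92e-05, or adjusted p = 0.224 with an estimated correlation. Cyp1a2 went from 609.6 ± 131 to 101 ± 26.4 CPM (log2 fold change -2.59, SE 0.18, adjusted p = 7.94e-10). Bile acid and xenobiotic genes had 3 higher and 16 lower of 22 measured members, or 3 and 17 adjusted over the list alone. Their median was -0.89 on the log2 scale, with camera adjusted p = 0.00135, and adjusted p = 0.347 with an estimated correlation. Slc10a1 fell (-1.75, SE 0.17) and Abcg5, which forms a sterol exporter with Abcg8, rose (2.10, SE 0.16). Male-biased liver genes had 0 higher and 13 lower of 14 measured members, the same adjusted over the list alone. The median was -2.72 (camera adjusted p = 2.57e-05, and adjusted p = 0.347 with an estimated correlation). C8b, a complement component, was at -2.94, SE 0.33.

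Lysosomal genes were in part higher on the diet. Lysosomal hydrolases had 20 higher and 8 lower of 45 measured members, the same adjusted over the list alone. A median of 0.20 gave camera adjusted p = 0.0125, or adjusted p = 0.601 with an estimated correlation. Cd63 rose from 2.14 ± 0.256 to 42.3 ± 14.1 CPM. The v-ATPase had 15 higher and 1 lower of 17 measured members, or 16 and 1 adjusted over the list alone. Their median was 0.36 on the log2 scale, with camera adjusted p = 0.00497, and adjusted p = 0.366 with an estimated correlation. MiT/TFE targets had 11 higher and 1 lower of 21 measured members, or 11 and 2 adjusted over the list alone. The median was 0.23 (camera adjusted p = 0.0225, and adjusted p = 0.519 with an estimated correlation). Beside these, markers of monocyte-derived macrophages, cells rich in lysosomes, had 13 higher and 0 lower of 14 measured members, the same adjusted over the list alone, with a median of 2.43. Autophagy genes had 6 higher and 11 lower of 31 measured members, the same adjusted over the list alone. A median of -0.03 gave camera adjusted p = 0.410, or adjusted p = 0.750 with an estimated correlation. Mitochondrial genes had 3 higher and 8 lower of 30 measured members, or 1 and 7 adjusted over the list alone. Their median was -0.14 on the log2 scale, with camera adjusted p = 0.252, and adjusted p = 0.774 with an estimated correlation. Acute phase genes had 9 higher and 5 lower of 18 measured members, or 11 and 5 adjusted over the list alone. The median was 0.81 (camera adjusted p = 0.152, and adjusted p = 0.750 with an estimated correlation). The list passed without chow replicate 4 (adjusted p = 0.0184). The fibrinogen gene Fgb fell (-0.93, SE 0.11) and Il1rn, the interleukin-1 receptor antagonist, rose (3.15, SE 0.31). The FLCN complex list had 6 higher and 0 lower of 14 measured members, the same adjusted over the list alone. A median of 0.21 gave camera adjusted p = 0.157, or adjusted p = 0.431 with an estimated correlation. ATF4 targets had 10 higher and 4 lower of 20 measured members, or 11 and 4 adjusted over the list alone. Their median was 0.74 on the log2 scale, with camera adjusted p = 0.0829, and adjusted p = 0.256 with an estimated correlation. Without a low-count filter it passed (adjusted p = 0.0307). Unfolded protein response genes had 0 higher and 8 lower of 17 measured members, or 0 and 4 adjusted over the list alone. The median was -0.40 (camera adjusted p = 0.132, and adjusted p = 0.750 with an estimated correlation). The last list passed without chow replicate 2 (adjusted p = 0.0405) and without a low-count filter (0.0158).

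**Figure D3:**
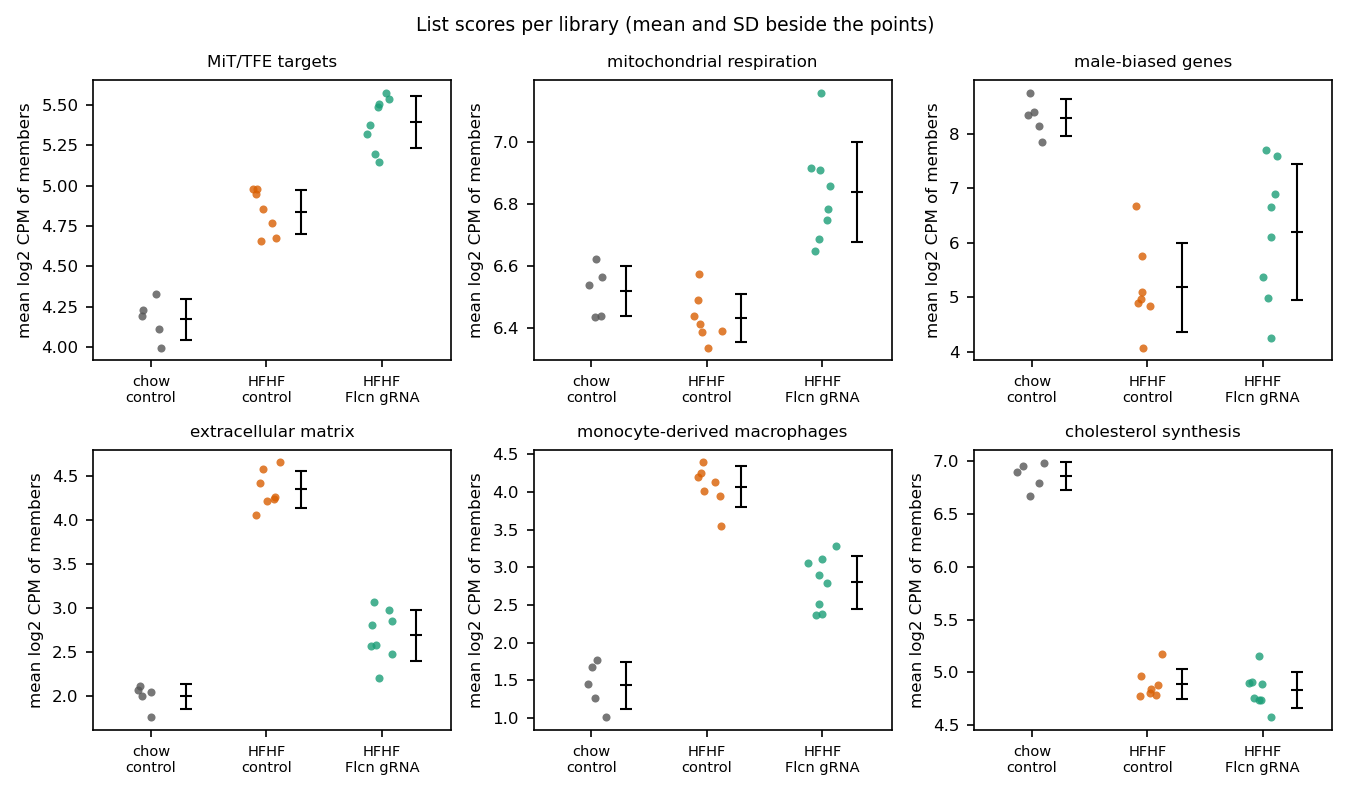
Score of 6 gene lists (mean log2 CPM of the members, vertical axis, not starting at 0) in each library of the 3 groups, with mean and SD beside the points. The extracellular matrix score was 4.34 in HFHF control and 2.69 with the gRNA, and the male-biased score was 8.29 in chow control and 5.18 in HFHF control.

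The third comparison sets the gRNA group on the HFHF diet against untreated chow. Fabp3 had 2 counts in the chow libraries and was 1290 times its chow level with the gRNA (95% counting interval 357 to 10650), and Sptlc3, a serine palmitoyltransferase subunit with 1 chow count, 821 times (147 to 32450). Without chow replicate 5, which held that count, the fitted log2 value of Sptlc3 went from 9.09 to 10.65, and with so few counts neither is a bound. Gpnmb was at 72.3 ± 34.9 CPM against 0.102 ± 0.0650 CPM (log2 fold change 9.36, SE 0.86, adjusted p = 2.50e-07). Sqle (log2 fold change -6.16, SE 0.30, adjusted p = 2.91e-11), Adgrf1 (-4.81, SE 0.46, and -5.75 without gRNA replicate 5) and Meg3, a long noncoding RNA (-4.35, SE 0.33), fell most. Omd, osteomodulin (log2 fold change 1.96, SE 0.12, adjusted p = 2.91e-11), and Abcg5 (log2 fold change 2.71, SE 0.16, adjusted p = 5.73e-11) had the smallest p among rises after Fabp3, and Msmo1, Cyp51 and Nsdhl had the smallest among falls, with Cyp51 at log2 fold change -3.35, SE 0.12, adjusted p = 2.20e-15. In all 2860 genes were higher and 2959 lower, 5819 or 42.6%, and 6864 had an unadjusted p under the same threshold. Upper-quartile scaling gave 55.6% higher calls in place of 49.1%. At least 2-fold changes were 832 higher and 363 lower. In 1231 genes every gRNA library lay above and in 1226 below every chow library, 18%, where chance gives 0.155%.

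Lists that kept their call with an estimated correlation in this contrast were cholesterol synthesis (0 higher and 25 lower of 25 measured members, the same adjusted over the list alone; median -1.88, camera adjusted p = 1.89e-82, adjusted p = 1.24e-05 with an estimated correlation), MiT/TFE targets (17 higher and 1 lower of 21 measured members, the same adjusted over the list alone; median 0.68, camera adjusted p = 9.53e-12, adjusted p = 0.0490 with an estimated correlation), the v-ATPase (16 higher and 0 lower of 17 measured members, the same adjusted over the list alone; median 0.61, camera adjusted p = 1.52e-11, adjusted p = 0.0398 with an estimated correlation) and lipid droplet genes (14 higher and 0 lower of 18 measured members, the same adjusted over the list alone; median 0.68, camera adjusted p = 8.01e-11, adjusted p = 0.0259 with an estimated correlation), besides the adipose list. The pancreas list passed too, but with 1 measured gene, Cela1, no correlation could be estimated, and it lost its call without a low-count filter (adjusted p = 0.0615). Hexa, a lysosomal hexosaminidase, rose from 30.6 ± 1.73 to 94.6 ± 16.4 CPM (log2 fold change 1.63, SE 0.11, adjusted p = 2.11e-10), and Rragd was at log2 fold change 4.71, SE 0.32, adjusted p = 3.00e-09. Lysosomal hydrolases had 32 higher and 2 lower of 45 measured members, or 34 and 3 adjusted over the list alone. A median of 0.53 gave camera adjusted p = 6.73e-15, or adjusted p = 0.0671 with an estimated correlation. The FLCN complex list had 8 higher and 2 lower of 14 measured members, the same adjusted over the list alone. Their median was 0.35 on the log2 scale, with camera adjusted p = 9.61e-04, and adjusted p = 0.0671 with an estimated correlation. Mitochondrial genes had 21 higher and 1 lower of 30 measured members, or 24 and 1 adjusted over the list alone. The median was 0.32 (camera adjusted p = 1.87e-04, and adjusted p = 0.476 with an estimated correlation). Fatty acid oxidation had 17 higher and 1 lower of 30 measured members, or 19 and 1 adjusted over the list alone. A median of 0.37 gave camera adjusted p = 5.75e-06, or adjusted p = 0.407 with an estimated correlation. Extracellular matrix genes were still higher than in chow in part, with 17 higher and 0 lower of 26 measured members, or 18 and 0 adjusted over the list alone, median 0.58, camera adjusted p = 5.17e-05, adjusted p = 0.407 with an estimated correlation, and the median stayed 0.58 with Timp1 at its bound (at least 8.49-fold higher). Monocyte-derived macrophage markers had 10 higher and 0 lower of 14 measured members, the same adjusted over the list alone. Their median was 1.24 on the log2 scale, with camera adjusted p = 3.92e-05, and adjusted p = 0.160 with an estimated correlation. Stellate markers had 5 higher and 0 lower of 12 measured members, the same adjusted over the list alone. The median was 0.31 (camera adjusted p = 0.0141, and adjusted p = 0.407 with an estimated correlation). Cell cycle genes had 13 higher and 0 lower of 20 measured members, or 15 and 0 adjusted over the list alone. A median of 0.69 gave camera adjusted p = 0.00156, or adjusted p = 0.407 with an estimated correlation. p53 targets had 11 higher and 2 lower of 16 measured members, the same adjusted over the list alone. Their median was 0.71 on the log2 scale, with camera adjusted p = 0.00890, and adjusted p = 0.407 with an estimated correlation. Lymphocyte markers had 10 higher and 0 lower of 16 measured members, or 11 and 0 adjusted over the list alone. The median was 0.93 (camera adjusted p = 0.00482, and adjusted p = 0.407 with an estimated correlation). Lipogenesis had 13 higher and 3 lower of 23 measured members, or 14 and 3 adjusted over the list alone. A median of 0.67 gave camera adjusted p = 0.00998, or adjusted p = 0.481 with an estimated correlation. Hepatocyte identity had 0 higher and 11 lower of 22 measured members, the same adjusted over the list alone. Their median was -0.33 on the log2 scale, with camera adjusted p = 0.00202, and adjusted p = 0.407 with an estimated correlation. Male-biased genes had 0 higher and 8 lower of 14 measured members, the same adjusted over the list alone. The median was -1.58 (camera adjusted p = 5.42e-04, and adjusted p = 0.476 with an estimated correlation). The acute phase list had a median of 0.08 and a mean of 0.21 with a camera direction of down (adjusted p = 0.640). The fructose list had a median of 0.17 and a mean of -0.01 with a direction of up (adjusted p = 0.0917, 0.0276 without chow replicate 1 and 0.0459 without a low-count filter). Unfolded protein response genes did not pass (adjusted p = 0.0584), and did without chow replicate 1, 2 or 3, HFHF control replicate 5, or gRNA replicate 1, 3 or 5 (adjusted p = 0.0184, 0.00933, 0.0139, 0.0478, 0.00897, 0.0418 and 0.0492), with upper-quartile factors (0.0468) and without a low-count filter (0.00673).

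The fourth comparison asks whether the gRNA moved genes changed by the diet back toward chow or further away. Across the 13667 genes the gRNA and diet fold changes had a Pearson correlation of -0.602 and a Spearman correlation of -0.618; genes are not independent replicates, so this describes the genes only. The HFHF control libraries are shared by both contrasts, and 20 simulated draws without any effect gave a mean correlation of -0.471. The covariance was -0.353 against -0.0192 simulated, a difference of -0.334. With the 7 HFHF controls split into 3 and 4, in 35 splits with both roles, the correlation was -0.597 to -0.495 (mean -0.550, SD 0.0260) and the mean covariance -0.340. Of 4000 genes called in both contrasts, 3720 (93%) moved in opposite directions and 280 in the same. Diet up with gRNA down held 2068 genes, where independent lists would share 731, and diet down with gRNA up 1652, where they would share 772. Up in both held 224 (752 from independent lists) and down in both 56 (750). The simulated draws gave 0 genes called in both. They hold no effect in either contrast, so this 0 does not measure what shared controls add among called genes. The split controls, where the contrasts share no HFHF control library, gave a mean of 2531 opposite (1867 to 2890) and 182 in the same direction (124 to 316). Of the 7794 diet-called genes 3212 were not called between gRNA and chow and 4582 were. The share of diet-raised genes that the gRNA lowered was 53.8%, and of diet-lowered genes that it raised 41.9%.

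The genes ranked here were called in both contrasts, and their groups' libraries overlapped in neither. They also had an assigned name and a mean of at least 2 log2 CPM in chow or HFHF control. Among them, the largest diet-raised genes that the gRNA lowered were Sprr1a, Sdcbp2, Shc2, Mmp12 and Cidec. Mmp12 was at 0.286 CPM in chow, 41.7 CPM in HFHF control and 5.26 CPM with the gRNA, and Cidec at 0.653, 80.3 and 44.6 CPM. Under the same conditions, the largest diet-raised genes that the gRNA raised further included Rragd (1.97, 13.5 and 51.8 CPM), Cln6, an endoplasmic reticulum protein needed for lysosomal enzyme supply (1.40, 8.11 and 31.9 CPM), the small heat shock protein gene Hspb1 (9.12, 27.2 and 63.0 CPM) and Renbp (1.69, 5.07 and 35.3 CPM). Gpnmb was not called with the gRNA (log2 fold change 0.65, SE 0.36, adjusted p = 0.172), and cholesterol synthesis genes stayed low, with Sqle at 1.16 CPM in HFHF control and 1.05 CPM with the gRNA.

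**Figure D4:**
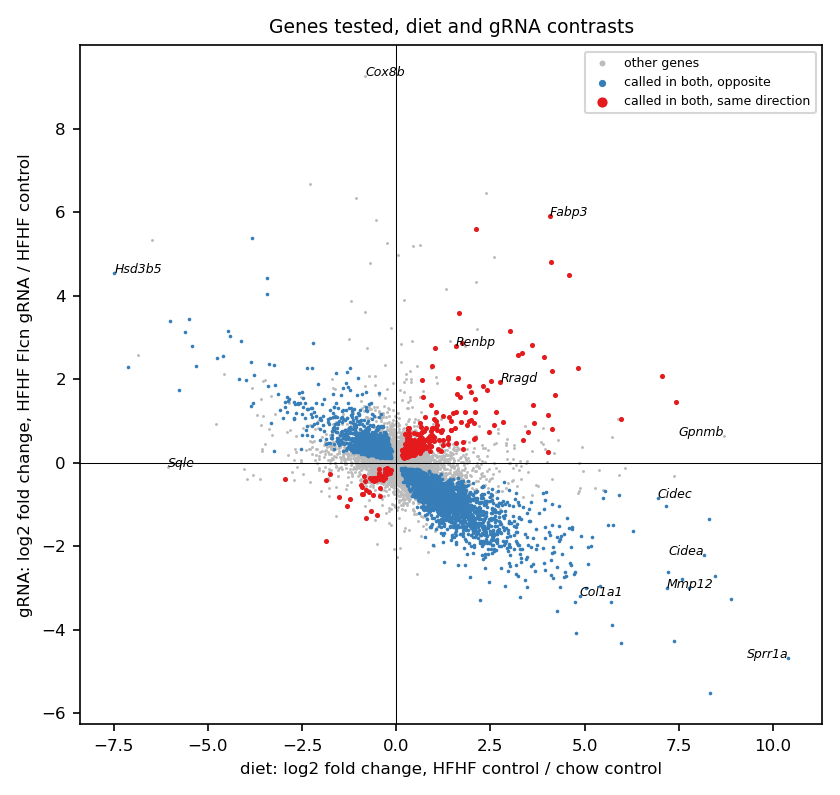
Log2 fold change of HFHF control against chow control (horizontal axis) and of HFHF Flcn gRNA against HFHF control (vertical axis) for each gene tested. Blue points are the 3720 genes called in both in opposite directions, red points the 280 called in both in the same direction, grey points the others; fitted values of genes without chow counts, such as Sprr1a, are no bounds.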

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

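The screen for libraries far from the rest of their group was fixed before the data were examined and run on the named genes, the list scores and the library totals, while the count of construct sequences was compared between groups after the table was seen. In 27 of 450 groups tested, or 6%, the highest or lowest library lay apart from the others by more than the 95% limit of Dixon's gap test, where chance gives 5% or about 1 in 20 groups. Of these, 9 were in HFHF control replicate 2.

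HFHF control replicate 2 was the highest of its group for 6 genes of large families: Mup7 at 997.5 CPM (others 12.3 to 70.2), Serpina1e at 318.6 CPM (others 35.2 to 99.4), Mup1 at 78.8 CPM (others 1.68 to 13), Mup11 at 51.7 CPM (others 2.86 to 11.3), Mup12 at 42.4 CPM (others 0 to 2.92) and Hsd3b5 at 7.38 CPM (others 0.05 to 1.01). It was also highest for Sqle (3.17 CPM, others 0.36 to 1.23), for Sptlc3 (1.89 CPM, others 0.06 to 0.67) and for the lipogenesis score (7.46, others 6.99 to 7.10). In the same group Kdr stood at 30.8 CPM in replicate 4 (others 17.2 to 21.1) and Sprr1a at 20.8 CPM in replicate 7 (others 6.09 to 12.4).

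In the gRNA group replicate 6 was highest for Cox8b (90.0 CPM, others 15.3 to 41.1) and Sptlc3 (33.1 CPM, others 5.99 to 11.6). Replicate 5 was highest for Cyp51 (27.8 CPM, others 16.6 to 21.7), Adgrf1 (1.52 CPM, others 0 to 0.37) and Krt19 (0.89 CPM, others 0.13 to 0.45). Replicate 7 was highest for Cbr3 (2.47 CPM, others 0.47 to 1.35) and for the neutrophil score (1.48, others 0.499 to 0.870), and replicate 8 lowest for the pancreas score (1.44, others 2.23 to 2.92).

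Among the chow libraries replicate 5 was highest for Nudt7 (757.4 CPM, others 463.5 to 532.7), Clock (93.9 CPM, others 85.3 to 87.6) and Sptlc3 (0.08 CPM, others 0) and lowest for the blood score (5.64, others 6.14 to 6.31). Replicate 1 was highest for Fnip1 (54.3 CPM, others 40.7 to 43.3) and Bex2 (0.07 CPM, others 0) and lowest for the cell cycle score (0.257, others 0.644 to 0.727). Replicate 4 was highest for Fgf21 (1.04 CPM, others 0.15 to 0.31).

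Among the construct sequences, which entered no comparison, PGK held 4.0031 estimated counts in the gRNA libraries (1.0019 in replicate 1, 1.0 in replicate 2 and 2.0012 in replicate 4) and Neo 1 count (replicate 7), against 0 in the control libraries, a difference that was not tested. LacZ held 2 counts, all in HFHF control libraries.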

How the results depend on the processing

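All of the alternatives were planned before the data were examined. Without the 2-fold minimum the counts of genes stayed within 1.5 times of those reported: 4814 to 5551 for the gRNA contrast, 7088 to 8179 for diet and 5173 to 5984 for gRNA against chow, and leaving out each library in turn gave 4632 to 5315, 7204 to 7855 and 5152 to 5921. With a 2-fold minimum they were 1059, 2370 and 1195, by construction of the threshold. Lists past camera were 16, 17 and 19 and fell to 1, 5 and 6 with an estimated correlation (the last with the pancreas list of 1 gene), while leaving out libraries gave 16 to 17, 16 to 18 and 19 to 21. The correlation of gRNA and diet fold changes was -0.686 over diet-called genes alone, a choice that shares the HFHF controls and has no simulated counterpart, and -0.550 with split controls, and -0.623 to -0.577 on leaving out libraries.

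Flcn against chow lost its call with DESeq2 size factors (-0.32, adjusted p = 0.0563), upper-quartile factors (-0.29, 0.0819), the DESeq2 Wald test (-0.32, 0.0620), limma-voom (-0.30, 0.0663), non-robust dispersion (-0.32, 0.0515), no filter (-0.31, 0.0793), a stricter filter (-0.29, 0.0775) and a fit of both groups alone (-0.31, 0.0880); the causes were not tested. It kept the call without the gRNA library of the different title (-0.35, 0.0421), and on leaving out each library it ranged from -0.38 to -0.12. In the gRNA contrast the range was -0.28 to -0.16 and in the diet contrast -0.16 to 0.11, where the sign changed only without chow replicate 1.

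Of 392 calls of named genes other than Flcn 21 were lost under at least 1 alternative, of 32 not called 15 were gained, and 0 reversed. Of 52 list calls 42 were lost under at least 1 alternative and of 50 not called 24 were gained, the losses mostly with the estimated correlation and the gains mostly with fry or without a low-count filter. With the gRNA, fry added the FLCN complex (fry adjusted p = 4.40e-04), ATF4 (6.42e-05), neutrophil (4.11e-05), clock (8.67e-04), p53 (0.0369), cholangiocyte (0.0182) and pancreas (6.96e-04) lists. On the diet it added the FLCN complex (7.81e-05), ATF4 (1.83e-06), neutrophil (1.37e-06), acute phase (0.0230), lipogenesis (0.0117), autophagy (0.0284), female-biased (0.0251) and pancreas (1.40e-05) lists. At 13974379 to 19586576 counts per library, the simulated test found 50.7 to 71.6% of genes changed 1.5-fold. Far fewer genes were changed there than were called in the data, so these shares do not measure the sensitivity of the real contrasts. Small changes can still be missed.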

Other observations

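The tests of explanations below, except that of sex-linked genes, and the count of genes over splits were chosen after the results were seen, and the tests of sex-linked genes and of list counts over splits before. Markers of other cells moved in several directions with the gRNA. Of Kupffer cell markers 4 of 12 measured members rose, 5 fell and 3 did not pass (the same counts adjusted over the list alone). A median of -0.30 gave camera adjusted p = 0.874, or adjusted p = 0.955 with an estimated correlation. The median was below 0 and the mean 0.14. Timd4, a marker of resident Kupffer cells, went from 5.43 ± 1.27 CPM in chow to 1.05 ± 0.671 in HFHF control and 5.08 ± 1.72 with the gRNA, with log2 fold change 2.27, SE 0.31, adjusted p = 9.97e-06. Marco went from 5.42 to 1.16 and 5.53 CPM, while the complement gene C1qb, which macrophages of several kinds express, went from 22 to 59.7 and 32.0 CPM. On the diet the Kupffer list had 5 higher and 2 lower of 12 measured members, the same adjusted over the list alone. Their median was 0.50 on the log2 scale, with camera adjusted p = 0.252, and adjusted p = 0.750 with an estimated correlation. Lymphocyte markers had 6 higher and 8 lower of 16 measured members, the same adjusted over the list alone with the gRNA (median -0.67, camera adjusted p = 0.819, adjusted p = 0.955 with an estimated correlation). The B cell genes Cd79a (1.18, SE 0.25) and Ms4a1 (1.24, SE 0.27) rose and the chemokine gene Ccl5 fell (-1.78, SE 0.29). On the diet this list had 10 higher and 1 lower of 16 measured members, the same adjusted over the list alone (median 1.79, camera adjusted p = 0.0368, adjusted p = 0.468 with an estimated correlation). That call was lost with upper-quartile factors (adjusted p = 0.0835) and without any 1 of chow replicate 1, 2, 4 or 5, HFHF control replicate 5, or gRNA replicate 1, 2, 3, 5 or 8 (adjusted p of 0.0516 to 0.0655). Neutrophil markers had 0 higher and 3 lower of 4 measured members, the same adjusted over the list alone with the gRNA (median -1.02, camera adjusted p = 0.0527, adjusted p = 0.220 with an estimated correlation; 0.0487, 0.0408 and 0.00502 without chow replicate 2, chow replicate 5 and gRNA replicate 7) and 3 higher and 0 lower of 4 measured members, or 4 and 0 adjusted over the list alone on the diet (median 1.56, camera adjusted p = 0.0519, adjusted p = 0.256 with an estimated correlation; 0.0361, 0.0484, 0.0183 and 0.0141 without chow replicate 5, HFHF control replicate 3, gRNA replicate 7 and a low-count filter). Cholangiocyte markers had 0 higher and 3 lower of 5 measured members, or 0 and 4 adjusted over the list alone with the gRNA (median -0.71, camera adjusted p = 0.182, adjusted p = 0.57 with an estimated correlation; 0.0135 without a low-count filter) and 3 higher and 1 lower of 5 measured members, the same adjusted over the list alone on the diet (median 1.04, camera adjusted p = 0.470, adjusted p = 0.750 with an estimated correlation), all at low levels: Krt19 was at 0.390, 1.10 and 0.413 CPM.

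Clock genes differed between HFHF control and chow. The list had 5 higher and 8 lower of 17 measured members, or 6 and 8 adjusted over the list alone (median 0.15, camera adjusted p = 0.514, adjusted p = 0.750 with an estimated correlation; median 0.15 and mean 0.27 with a camera direction of down), with Dbp at log2 fold change 3.89, SE 0.73, adjusted p = 2.11e-04, Clock at log2 fold change -0.94, SE 0.10, adjusted p = 7.38e-08 and Nfil3 at log2 fold change -1.48, SE 0.27, adjusted p = 1.49e-04. With the gRNA it had 4 higher and 0 lower of 17 measured members, or 3 and 0 adjusted over the list alone (median 0.17, camera adjusted p = 0.106, adjusted p = 0.300 with an estimated correlation; 0.0260 without a low-count filter), and Hlf was at 0.64, SE 0.10. The median and camera look for a shift in 1 direction, so they cannot show a change in which members move both ways. The hour of sampling is not given in the sources used here, so whether it differed between the groups is not known. Female-biased liver genes had 3 higher and 0 lower of 7 measured members, the same adjusted over the list alone on the diet (median 1.52, camera adjusted p = 0.252, adjusted p = 0.750 with an estimated correlation) and 0 higher and 2 lower of 7 measured members, the same adjusted over the list alone with the gRNA (median 0.31, camera adjusted p = 0.772, adjusted p = 0.955 with an estimated correlation; mean -0.13, direction down), where Cyp17a1 fell (-1.54, SE 0.26). Blood transcripts had 1 higher and 1 lower of 5 measured members, the same adjusted over the list alone on the diet (median 0.69, camera adjusted p = 0.992, adjusted p = 0.996 with an estimated correlation; direction down) and 1 higher and 0 lower of 5 measured members, the same adjusted over the list alone with the gRNA (median -0.36, camera adjusted p = 0.855, adjusted p = 0.955 with an estimated correlation), and reads of the paired globin genes can be shared. Of 11 pancreas transcripts only Cela1, which was at 21.4, 9.10 and 5.01 CPM, was measured, and it fell with diet (-1.23, SE 0.18) and gRNA (-0.86, SE 0.17; list camera adjusted p = 0.181). Adipose transcripts had 3 higher and 0 lower of 4 measured members, the same adjusted over the list alone on the diet (median 2.90, camera adjusted p = 0.00119, adjusted p = 0.0452 with an estimated correlation; 0.0724 without a low-count filter) and 2 higher and 2 lower of 4 measured members, the same adjusted over the list alone with the gRNA (median -0.08, camera adjusted p = 0.819, adjusted p = 0.955 with an estimated correlation; mean 0.38, direction down), and 2 of the 4 measured, Cidec and Fabp4, are also in the lipid droplet list.

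MiT/TFE target and lysosomal hydrolase and membrane protein genes were higher with the gRNA as lists, though 10 of 21 and 17 of 45 measured members did not pass, 2 lysosomal members fell, and both calls were lost with an estimated correlation (camera adjusted p = 0.220 and 0.228). More monocyte-derived macrophages would raise their markers too, but that score changed by -1.27 (exact permutation p = 0.000155, the smallest that 6435 regroupings can give), whereas the Kupffer score changed by 0.128 (exact permutation p = 0.539) with members moving both ways, so a contribution of more resident Kupffer cells cannot be told apart. A larger share of hepatocyte RNA would raise MiT/TFE targets and hepatocyte genes alike. The MiT/TFE score rose by 0.316 more than 12 hepatocyte genes of at least 1000 CPM (exact permutation p = 0.0353). Those 12 genes did not move together, from -0.33 for Trf to 0.79 for Cyp2e1, so a larger hepatocyte share is not excluded. For lysosomal genes alone the difference was 0.0406 (exact permutation p = 0.716), so their rise cannot be told apart from a change in hepatocyte share. The vector or guide itself may also raise the MiT/TFE score (0.556), and no group received vector without this guide, so this too cannot be told apart. An effect through loss of folliculin stays open as well and was not tested.

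Matrix and monocyte-derived macrophage genes were lower with the gRNA. With an estimated correlation the matrix list kept its call (camera adjusted p = 0.00988), while the macrophage list, of which 4 of 14 measured members did not pass, lost it (adjusted p = 0.148). A lower share of all cells other than hepatocytes would lower endothelial and monocyte-derived macrophage markers alike, if both lists were equally specific. That was not tested. The endothelial score minus the macrophage score was 1.38 higher with the gRNA (exact permutation p = 0.000155, the smallest possible), as the list medians had already shown. Such a lower share would not alone give this value under that condition, but it is not excluded beside another change. Fewer stellate cells in an unchanged state would lower matrix and stellate scores alike if both lists were equally specific to these cells, which was not tested. The matrix score minus the stellate score changed by -1.03 (exact permutation p = 0.000155, the smallest possible), a difference that the list medians had already shown. So this value does not exclude fewer stellate cells. A change in the state of matrix-producing cells, fewer monocyte-derived macrophages and an effect of the vector stay open and were not tested.

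Male-biased liver genes were lower on the diet (13 of 14 measured members), a list call that was lost with an estimated correlation (camera adjusted p = 0.347, from 2.57e-05 with the preset one). Female animals among the diet controls would lack Y-linked transcripts, but the lowest sum of 4 Y-linked genes there was 120.3 CPM, and Xist reached at most 0.215 CPM in the 20 libraries. Reads shared between paralogs would leave members outside large families in place, but the median of 6 such members was -2.27. With 13 of 14 members called lower, this was largely known beforehand. A general fall of hepatocyte transcripts would move both scores alike, but the male-biased score fell by 2.40 more than the hepatocyte identity score (exact permutation p = 0.00253). The list medians had already shown this difference, and a general fall beside another change is not excluded. An effect of the diet itself, or of the vehicle injection that goes with it, stays open and was not tested.

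Other splits of the libraries into groups of the same sizes were drawn 100 times per contrast, the real one included, with the 2 groups fitted alone. The real split called 4886 genes for gRNA against HFHF control, 7861 for diet and 5173 for gRNA against chow. The highest other splits called 1484, 1937 and 1699, with a median of 0 in each contrast. In each contrast 1 of the 100 splits, the real one, gave as many, of 6435, 792 and 1287 possible splits. Mixed splits add the group difference to the spread within groups, which lowers their calls. So for the gene counts a chance split is unlikely but not excluded. Regrouping also cannot show whether libraries come from separate animals. For the number of gene lists past camera with the preset correlation, the real splits did not stand apart, so chance is not excluded there either. The real splits gave 17, 17 and 19 lists, the highest other splits 21, 23 and 24, and 16, 25 and 10 of the 100 splits gave as many.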
